A study of Danio rerio with 18 samples.

How the data were processed

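The authors deposited a separate table for each of 3 times, with 34326 genes in each. Per the file headers they hold total counts from paired, trimmed reads and TPM, and all values given here rest on the deposited counts unless TPM is named. Per the labels the libraries were made with SMART-Seq v4 and Nextera XT from sorted cells, and larvae were kept in 1.5X phenylthiourea, which blocks melanin formation, from 0.25 to 5 dpf. Gene positions follow GRCz10. The aligner, the counting program and the annotation release are not given in the sources used here. Counts of near-identical gene copies, such as her4.2, crystallin and opsin genes, therefore rest on a counting rule that is not known.

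All 18 columns of counts were matched to a sample, and none was left without a group. The label of unablated 4 dpi replicate 1 gives it as unablated (MTZ-), while its sequencing name contains the word positive. The label was followed. Over the 452 genes called in the separate 2 dpi libraries this pair differed as labelled in 96.5% of genes, with a median aligned log2 difference of 1.74, and il11b stood at 0.228 CPM in the unablated and 40.1 CPM in the ablated library. Fits lacking that library and lacking all first replicates were run. Groups, contrasts, main tests and the alternatives listed at the end of this part were fixed before the data were examined. Tests and alternatives added later are given as such where they are used.

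Genes with low counts were removed with filterByExpr of edgeR by group, which left 20093 of 29481 genes with a count. Libraries were scaled by TMM. A quasi-likelihood model with robust dispersion in edgeR 4.0.16 held 6 group means over all 18 libraries, with 12 residual degrees of freedom and a common biological coefficient of variation of 79.9%. Contrasts were ablated minus unablated at each time, the differences of these effects between times, and unablated 7 minus 2 dpi. Adjusted p is Benjamini-Hochberg over all tested genes with a threshold of 0.05. Other versions were R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and, for reading files, data.table in version 1.17.8.

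Replicate numbers were tested as pairs. After group means were removed, the correlation of an ablated library with the unablated library of its own number was 0.187 to 0.593, and the highest with another number was 0.183. The block used in the text is the same model with these 9 pairs added, which leaves 6 residual degrees of freedom. It removes the unablated time contrast, so that contrast was not run with it. The sequencing names of replicates 2 and 3 hold a date string that is shared within each pair, and those of replicate 1 hold none. Replicates 2 and 3 at 2 dpi share a date, and so do replicates 2 at 4 and 7 dpi.

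Gene lists were written from general knowledge of zebrafish eye, immune and stress genes, 28 lists with 772 symbols, of which 733 matched a gene and 638 were tested. A symbol carried by 2 gene IDs makes the cell cycle list 33 symbols and 34 measured genes, and 11 genes stand in more than 1 list. The result of 1 list, which was called at 2 dpi at the preset correlation but not with an estimated one, and of some single genes is left out of the text. Each list was tested with camera of limma on log2 CPM with a prior count of 2, at a preset correlation between genes of 0.01, and adjusted over all lists and the 3 ablation contrasts. Lists for differences between times and for unablated time were adjusted within those sets. Members were counted over all genes and again adjusted over the list alone. Camera with a correlation estimated from the data, and fry, a rotation test, were run beside it. The block changed list calls at 2 dpi for RPE and ribosomal protein genes, at 4 dpi for interferon genes and at 7 dpi for ribosomal protein genes. No list passed with the block and an estimated correlation, where the lowest adjusted p was 0.57.

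Genes were named by a rule, applied to the fit without the block and again to the block. At each time it took the 10 largest rises and 10 largest falls by log2 fold change among genes past the threshold that had a symbol other than a clone name, all ablated libraries on one side of all unablated ones, and a higher group mean of at least 5 CPM. Without the block 249 genes were eligible as rises and 133 as falls at 2 dpi, and 9 and 6 at 4 dpi. From each list it took up to 4 members past the threshold by adjusted p, or up to 2 members by level where none passed, and rpe65a always. For differences between times it took the 5 smallest adjusted p in each direction. Where 1 group had no count the fold is a floor that grants 3 counts per library, and where it had 1 to 3 counts the ratio carries a 95% counting interval.

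The pipeline was tested on simulated data with 50 changed genes for each of 4 fold sizes among 19546 genes. At 2 dpi edgeR found 14%, 58%, 86% and 94% of 4-fold, 8-fold, 16-fold and 32-fold changes, with 6 false calls. The block made 0 to 5 false calls, voom 3 to 9 and DESeq2 80 to 89. A list moved 8-fold was found (adjusted p = 6e-30, and 1.4e-06 with an estimated correlation), with 0 of 83 other list tests called. Simulated genes were drawn independently and without pair effects. The simulation therefore cannot show how often lists of correlated genes, or genes in the block with real pairs, are called falsely.

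Alternatives were DESeq2 size factors, no filter apart from a total above 0, the DESeq2 Wald test, voom with quality weights and without TMM factors, a fit of only the times compared, the block, all groups lacking their first replicate, limma trend on log2 of the deposited TPM plus 1, and leaving out each library in turn. Overlaps were tested by the hypergeometric distribution, and single values per library by exact permutation.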

Results

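Bulk RNA-seq was made from cells that carried green fluorescent protein (eGFP) and were sorted from dissociated eyes of larval zebrafish. Up to 1000 cells went into each library, and the labels give the sorted cells as retinal pigment epithelium (RPE), the pigmented layer behind the retina that recycles visual chromophore. The RPE had been ablated by exposing larvae to 10 mM metronidazole for 24 h from 5 to 6 days post fertilisation, and unablated larvae served as controls. The labels give no group that received the drug without ablation. Effects of the drug and of ablation therefore cannot be told apart, and changes by ablation given here cover both. Bulk libraries also do not show whether a level changed within cells or the mix of sorted cells changed. Rises and falls given here can be either. Cells were taken 2, 4 and 7 days post-injury (dpi), which gave 6 groups of 3 libraries and 18 libraries in all. Levels are CPM (counts scaled to library size) as mean ± SD over the 3 libraries of a group, and log2 fold changes carry a standard error (SE).

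Total counts ran from 21.9 to 60.4 M per library. They lay between 28.9 and 40.5 M at 2 dpi, between 30.7 and 60.4 M at 4 dpi, and between 21.9 and 36.5 M at 7 dpi. Mitochondrially encoded genes took 10.3% ± 3.75 (SD, n = 3) of counts in unablated and 7.94% ± 3.14 in ablated libraries at 2 dpi. They took 4.92% ± 0.946 and 5.16% ± 1.57 at 4 dpi, and 7.25% ± 3.08 and 11% ± 0.723 at 7 dpi. Exact permutation tests of this share, taken on both sides, gave p = 0.5, 0.9 and 0.2 at 2, 4 and 7 dpi, and 3 libraries against 3 can give no p under 0.1. Replicates of a group correlated at r = 0.779 to 0.943 across genes, lowest among the ablated 7 dpi libraries. Genes are not independent replicates in any correlation or overlap given here. Nothing in the labels says that replicates came from separate clutches, so each p-value measures the spread between these libraries alone.

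The comparison of ablated with unablated larvae at 2 dpi asked how the sorted cells differed shortly after injury. il11b, an interleukin of the IL-6 family (ENSDARG00000058557, chromosome 19, 10509147 to 10520900 in GRCz10), went from no count in any unablated library to 163 ± 84.2 CPM, at least 1510-fold higher (adjusted p = 0.015). cxcl18b, a chemokine gene (ENSDARG00000075045, chromosome 1, 48577744 to 48581470), rose from 31.8 ± 4.82 to 1360 ± 923 CPM, a log2 fold change of 5.42 (SE 1.06, adjusted p = 0.018). hbegfa, which encodes a ligand of the epidermal growth factor receptor (ENSDARG00000075121, chromosome 14, 6742203 to 6745213), rose from 18.9 ± 3.3 to 146 ± 19.7 CPM, a log2 fold change of 2.95 (SE 0.52, adjusted p = 0.016).

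Other signal genes rose at 2 dpi from almost nothing. The endothelin gene edn2 (chromosome 19, 15372351 to 15377634) reached 26.7 ± 9.26 CPM, at least 246-fold above unablated libraries that held no count of it (adjusted p = 0.023). The leptin gene lepb and the serum amyloid gene saa were at least 55.3-fold and 98.4-fold higher (adjusted p = 0.031 and 0.032). saa ranged from 0.848 to 24.6 CPM between the ablated libraries. dkk1a, which encodes a secreted Wnt antagonist, rose to 25.2 ± 11.8 CPM, with a ratio of means of 1690 and a 95% counting interval from 423 to 93200 (adjusted p = 0.016). il34, a ligand of the colony stimulating factor receptor of macrophages, rose to 19 ± 9.97 CPM, with a ratio of 1470 and an interval from 329 to 72500 (adjusted p = 0.037). clcf1, a cytokine that shares the gp130 receptor chain with IL-6, had a ratio of 628 and an interval from 119 to 3580 (adjusted p = 0.028). The transcription factor gene sall1b was at least 47.8-fold higher (adjusted p = 0.036), ano5b had a ratio of 245 with an interval from 71.6 to 1020 (adjusted p = 0.045), and lipib rose from 0.047 ± 0.0613 to 20.1 ± 21.5 CPM (adjusted p = 0.04). Intervals and floors of 3 counts per library cover counting error only.

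**Figure D1:**
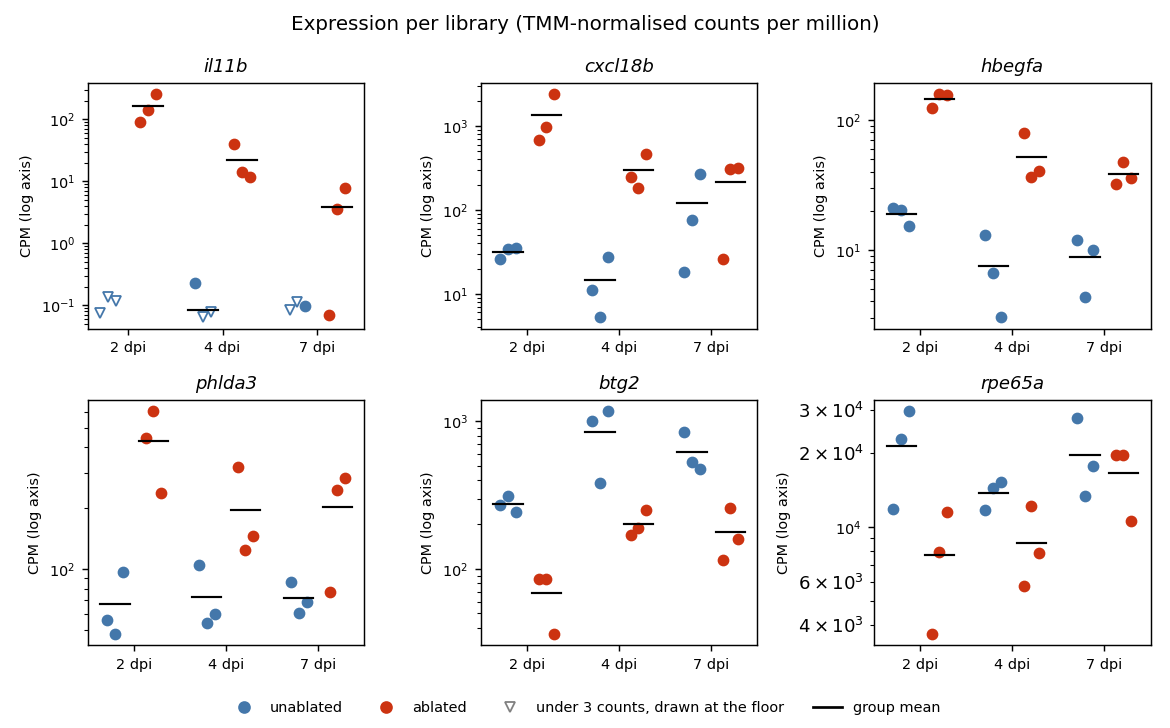
Level in each library (CPM, log axis) of il11b, cxcl18b, hbegfa, phlda3, btg2 and rpe65a at 2, 4 and 7 dpi, by ablation; black lines are group means over 3 libraries and open triangles mark libraries under 3 counts, drawn at that floor. il11b had no count in unablated 2 dpi libraries and a mean of 163 CPM in ablated ones.

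The largest falls at 2 dpi included the cytochrome gene cyp1b1, from 5.01 ± 0.559 to 0.0854 ± 0.00944 CPM, a log2 fold change of -5.84 (SE 0.95, adjusted p = 0.015). The receptor gene gpr182 fell from 74 ± 53.3 to 0.591 ± 0.756 CPM, a log2 fold change of -7.00 (SE 1.41, adjusted p = 0.02). ch25hl1.1, a cholesterol 25-hydroxylase-like gene, fell from 120 ± 97.5 to 1.68 ± 2.3 CPM (log2 fold change -6.17, SE 1.39, adjusted p = 0.031). The calcium pump gene atp2b2, the spectrin gene sptbn5 and the matrix gene spon1a fell by 6.75, 5.66 and 5.70 on the log2 scale (adjusted p = 0.037, 0.023 and 0.026). The transcription factor gene zic2a fell by 7.75 (SE 1.90, adjusted p = 0.042). The chemokine receptor gene cxcr4b had a ratio of 500 with an interval from 145 to 2070 (adjusted p = 0.034), and ran from 2.12 to 43.4 CPM between unablated libraries. The muscle genes tpma and ckma also fell, with ratios of 3080 and 3060 and intervals from 813 to 24300 and from 526 to 116000 (adjusted p = 0.047 and 0.036). Both were decided mostly by unablated replicate 1, which held 152 CPM of tpma and 76 CPM of ckma, while the other unablated libraries held at most 1.44 and 0.18 CPM.

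By gene list, cytokines and chemokines moved upward as a group at 2 dpi. Of 24 measured members 4 rose, il11b, il34, clcf1 and cxcl18b, none fell, and 6 rose adjusted over the list alone (camera adjusted p = 0.00084, adjusted p = 0.38 with an estimated correlation). The pair-blocked fit called 7 higher and 1 lower. In the injury response and JAK/STAT list 2 of 32 members rose, hbegfa and lepb, and 10 adjusted over the list alone (adjusted p = 0.0037, adjusted p = 0.56 with an estimated correlation). With the block 12 members were higher and 3 lower, among them socs3b, a feedback inhibitor of JAK/STAT signalling, at 152 ± 164 against 22.1 ± 25 CPM (adjusted p = 0.089, blocked adjusted p = 0.00031). Of 24 interferon response genes irf9 and isg15 rose, the count was also 2 adjusted over the list alone, 2 were higher and 2 lower with the block, and the list did not pass (adjusted p = 0.57). isg15 went from 0.717 ± 0.698 to 30.1 ± 16.9 CPM (log2 fold change 5.35, SE 1.29, adjusted p = 0.039).

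Among single genes that passed at 2 dpi, mdm2, a ubiquitin ligase gene, rose from 29.9 ± 1.63 to 105 ± 24.1 CPM (log2 fold change 1.81, SE 0.35, adjusted p = 0.016). phlda3, which encodes an inhibitor of Akt signalling (ENSDARG00000037804, chromosome 23, 5822470 to 5825270), rose from 66.8 ± 26.3 to 430 ± 185 CPM (log2 fold change 2.69, SE 0.55, adjusted p = 0.02). gadd45aa, a growth arrest gene, rose from 17.3 ± 4.02 to 157 ± 134 CPM (log2 fold change 3.18, SE 0.61, adjusted p = 0.016), and the initiator caspase gene casp8 rose by a log2 fold change of 2.30 (SE 0.57, adjusted p = 0.044). The cyclin gene ccng2 fell from 599 ± 179 to 84.5 ± 30.9 CPM (log2 fold change -2.83, SE 0.55, adjusted p = 0.017).

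In the heat shock and dissociation response list hspd1, a mitochondrial chaperonin, rose from 15.8 ± 6.46 to 149 ± 23.1 CPM (log2 fold change 3.24, SE 0.64, adjusted p = 0.019) and btg2, an early-response antiproliferative gene, fell from 275 ± 34 to 68.9 ± 28.5 CPM (a 3.99-fold fall, log2 SE 0.49, adjusted p = 0.041). That was 1 higher and 1 lower of 20, 3 and 1 adjusted over the list alone, and 6 and 1 with the block. The list as a whole did not pass (adjusted p = 0.074), and leaving out ablated replicate 1, unablated replicate 2, unablated replicate 3 or ablated replicate 3 gave 0.048, 0.037, 0.027 and 0.041. Oxidative phosphorylation genes were higher in 39 of 40 cases, with a median log2 fold change of 0.53 (adjusted p = 0.011, adjusted p = 0.65 with an estimated correlation). cycsb, a cytochrome c gene, rose from 376 ± 140 to 1490 ± 560 CPM (log2 fold change 1.99, SE 0.49, adjusted p = 0.043), the 1 member that passed both over all genes and adjusted over the list alone, and 7 passed with the block. Without unablated replicate 1, ablated replicate 2 or ablated replicate 3 that list gave adjusted p = 0.59, 0.085 and 0.32.

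Genes of the RPE itself did not pass at 2 dpi without the block. rpe65a, the isomerase of the visual cycle (ENSDARG00000007480, chromosome 2, 2316199 to 2331029), stood at 7710 ± 3940 CPM in ablated and 21400 ± 9010 CPM in unablated libraries (log2 fold change -1.48, SE 0.53, adjusted p = 0.15). With the block it fell by 1.53 (SE 0.27, blocked adjusted p = 0.0042). rlbp1b, which encodes a retinaldehyde-binding protein, stood at 12600 ± 5640 against 34900 ± 11800 CPM (adjusted p = 0.18, blocked adjusted p = 0.013). Of 20 RPE and visual cycle genes none was called, also adjusted over the list alone, and with the block 6 were lower. The list gave adjusted p = 0.053 without the block and 0.015 with it, and adjusted p = 0.57 and 0.63 with an estimated correlation. It gave 0.015 and 0.014 without unablated replicate 1 or ablated replicate 3. Its median log2 fold change was -0.58, or -0.45 with the member that had no count in 1 group at its bound. Melanin synthesis genes had a median of -0.42 over 18 genes (-0.41 at their bound), no call (adjusted p = 0.27), and 2 higher and 4 lower with the block.

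Markers of the neural retina and of developing eye stood lower in ablated libraries at 2 dpi. Of 28 eye field and retinal progenitor genes 1 was higher than in unablated libraries by sign, and the median log2 fold change was -3.05 (adjusted p = 9.6e-09, adjusted p = 0.56 with an estimated correlation). Over all genes 1 member was called lower, 17 members were lower and 1 higher adjusted over the list alone, and 16 were lower with the block. Photoreceptor markers had a median of -2.52 over 36 genes, with none called over all genes or adjusted over the list alone and 7 lower with the block (adjusted p = 4e-05, adjusted p = 0.58 with an estimated correlation). Their summed level was 436 to 2500 CPM in unablated and 260 to 358 CPM in ablated libraries. Retinal neuron markers had a median of -2.08 over 23 genes (adjusted p = 0.0038, adjusted p = 0.57 with an estimated correlation). Among them vsx1, a bipolar cell factor, fell from 20.8 ± 18.2 to 1.54 ± 0.888 CPM (log2 fold change -3.75, SE 0.92, adjusted p = 0.043), a call that the block ended (blocked adjusted p = 0.061). Adjusted over the list alone 4 retinal neuron markers were lower and 1 higher, and with the block 3 were lower and 1 higher.

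Mueller glia markers had a median of -1.33 over 14 genes at 2 dpi (adjusted p = 0.024, adjusted p = 0.38 with an estimated correlation, and 0.05 without ablated replicate 3). None was called over all genes, 3 were lower adjusted over the list alone, and 4 with the block. glula, a glutamine synthetase gene, stood at 489 ± 384 against 2770 ± 2310 CPM (adjusted p = 0.065, blocked adjusted p = 0.00018). Lens markers were lower in all 18 cases, with a median of -3.17 and no call (adjusted p = 0.00018, adjusted p = 0.57 with an estimated correlation). Cell cycle genes were lower in 33 of 34 cases, with a median of -1.77, no call over all genes or over the list alone, and 2 lower with the block (adjusted p = 0.00091, adjusted p = 0.65 with an estimated correlation). Their summed level was highest in unablated replicate 2, at 6980 CPM, against 1650 and 3690 CPM in the other unablated and 1100 to 2180 CPM in the ablated libraries.

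The lists that follow did not pass at 2 dpi with all libraries. Adjusted p was 0.27 for complement, 0.52 for macrophage and microglia markers, 0.17 for neutrophil markers, 0.67 for lymphocyte markers, 0.39 for other pigment cells and 0.14 for erythrocytes. It was 0.84 for endothelial markers, 0.062 for keratinocyte and corneal epithelium markers, 0.23 for fibroblast and periocular mesenchyme markers, 0.28 for epithelial to mesenchymal transition and matrix genes and 0.79 for Wnt targets and antagonists. Lysosome and phagocytosis genes gave 0.79, cholesterol synthesis genes 0.53 and ribosomal proteins 0.083. Ribosomal proteins were higher in 49 of 51 cases, with a median of 0.48, and passed with the block (blocked adjusted p = 9.3e-05), but not with the block and an estimated correlation, which was 0.967 without the block (blocked adjusted p = 0.74). Some of these depended on single libraries, since macrophage markers passed without unablated replicate 2 (adjusted p = 0.038), downward. Keratinocyte markers passed downward without unablated replicate 2, ablated replicate 2 or unablated replicate 3 (adjusted p = 0.034, 0.023 and 0.0014), and ribosomal proteins at 2 dpi upward without ablated replicate 1, unablated replicate 2 or unablated replicate 3 (2.2e-08, 6e-04 and 0.00026). Endothelial markers had a positive median, 0.17, with a negative mean, -0.55, and Wnt genes a median of -0.42 with a mean of 0.26. Matrix genes had a median of -0.06, a mean of 0.29 and an upward test.

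**Figure D2:**
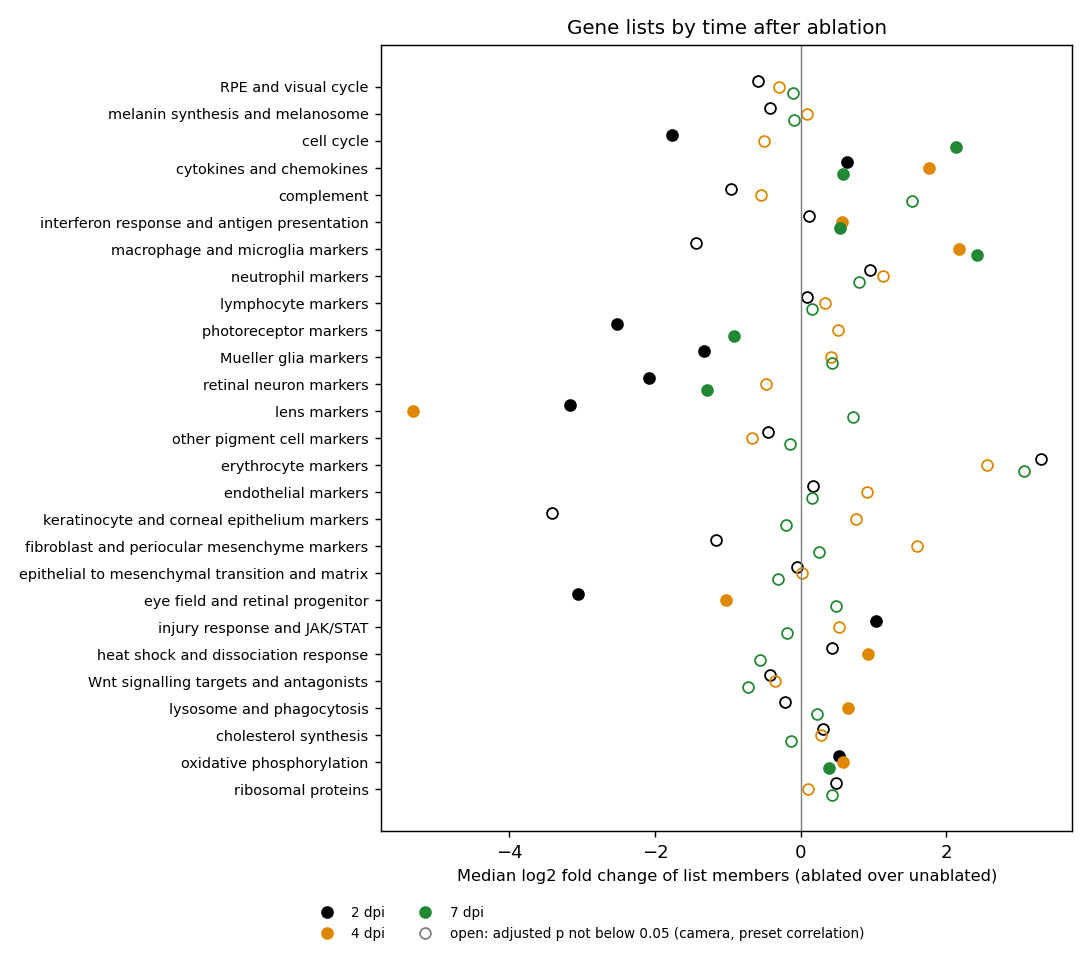
Median log2 fold change (ablated over unablated) of gene lists at 2, 4 and 7 dpi; filled points mark lists with a camera adjusted p below 0.05 under the preset correlation. Eye field genes had a median of -3.05 at 2 dpi, and macrophage markers medians of 2.18 and 2.41 at 4 and 7 dpi.

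In the edgeR test 452 of 20093 genes passed at 2 dpi, 280 higher and 172 lower, and 3312 had an unadjusted p under 0.05. With replicate numbers as pairs the block called 2901 genes, 1520 higher and 1381 lower, and kept 450 of the 452. The count was 138 without unablated replicate 1, 252 without ablated replicate 1, 19 without unablated replicate 2, 89 without ablated replicate 2, 60 without unablated replicate 3 and 233 without ablated replicate 3, and the share of higher genes among these ran from 10.5% to 73.4%. Of the 34 calls of genes chosen by the naming rule 2 to 16 were kept when 1 of these libraries was left out. The share of higher genes was 61.9% and 74.5% when tested on TPM. With voom, which was run without TMM factors, the median log2 fold change of all genes moved from -0.03 to 0.10.

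At 4 dpi, in the next comparison of ablated with unablated larvae, genes of the secretory pathway were among those that rose. manf, an endoplasmic reticulum stress factor (ENSDARG00000063177, chromosome 22, 32274258 to 32280927), rose from 7.95 ± 1.88 to 53.1 ± 2.58 CPM, a log2 fold change of 2.74 (SE 0.42, adjusted p = 0.033). The calreticulin gene calr3b rose from 14.9 ± 6.57 to 137 ± 20.2 CPM (9.17-fold, log2 SE 0.57, adjusted p = 0.047). nucb2b, which encodes a nucleobindin (ENSDARG00000036291, chromosome 18, 38210338 to 38229084), rose from 3.05 ± 1.98 to 62.8 ± 15.9 CPM (log2 fold change 4.36, SE 0.67, adjusted p = 0.033). hbegfa rose again, from 7.54 ± 5.02 to 51.6 ± 23.3 CPM (log2 fold change 2.77, SE 0.51, adjusted p = 0.049).

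Further rises at 4 dpi were in vmp1, an autophagy gene, from 19.5 ± 2.96 to 125 ± 67.2 CPM (adjusted p = 0.047), in aanat1, a gene of melatonin synthesis, from 1.34 ± 0.323 to 14 ± 5.04 CPM (adjusted p = 0.047), and in abracl, from 14.4 ± 7.75 to 142 ± 13.2 CPM (adjusted p = 0.033). glod5 rose from 3.55 ± 0.886 to 33.5 ± 13.8 CPM (adjusted p = 0.047), and the scavenger receptor gene scara3 by a log2 fold change of 7.02 (SE 1.26, adjusted p = 0.047). The amino acid transporter gene slc43a2b (ENSDARG00000061120, chromosome 10, 24403277 to 24422264) fell from 1830 ± 1230 to 114 ± 39 CPM, a log2 fold change of -4.01 (SE 0.73, adjusted p = 0.047). The collagen gene col9a1a fell from 79 ± 39.8 to 10.1 ± 1.69 CPM (log2 fold change -2.96, SE 0.51, adjusted p = 0.047). phyhipla, tnk2b and gatsl2 fell by 3.05, 2.65 and 1.96 on the log2 scale (adjusted p = 0.036, 0.047 and 0.047).

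Cytokines and chemokines again stood higher as a group at 4 dpi, with a median log2 fold change of 1.76 over 24 genes, or 1.39 with members that had no count in 1 group at their bound (adjusted p = 0.00027, adjusted p = 0.38 with an estimated correlation). None passed over all genes, 3 were higher adjusted over the list alone, and 6 with the block. il11b stood at 22 ± 15.6 against 0.0848 ± 0.125 CPM (adjusted p = 0.058, blocked adjusted p = 0.00071) and cxcl18b at 299 ± 149 against 14.5 ± 11.4 CPM (adjusted p = 0.085, blocked adjusted p = 0.00082). Interferon response genes passed as a list (adjusted p = 0.031, adjusted p = 0.56 with an estimated correlation), but not with the block (blocked adjusted p = 0.095) or without unablated replicate 2 (adjusted p = 0.16). None of the 24 was called over all genes, and 2 were higher adjusted over the list alone and also with the block.

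Macrophage and microglia markers were higher in 28 of 32 cases at 4 dpi, with a median of 2.18 (adjusted p = 6.7e-05, adjusted p = 0.58 with an estimated correlation). No member was called over all genes or over the list alone, and 1 with the block. apoeb, an apolipoprotein gene abundant in macrophages and microglia, stood at 2590 ± 603 against 175 ± 237 CPM and did not pass (log2 fold change 3.89, SE 1.32, adjusted p = 0.23, blocked adjusted p = 0.056). Lysosome and phagocytosis genes had a median of 0.64 over 31 genes (adjusted p = 0.014, adjusted p = 0.57 with an estimated correlation, and 0.053 without unablated replicate 3), with no call over all genes, and 4 higher and 1 lower with the block. Heat shock genes had a median of 0.92 (adjusted p = 0.03, adjusted p = 0.57 with an estimated correlation). None of the 20 was called over all genes, and 4 were higher and 2 lower both adjusted over the list alone and with the block. That list gave 0.12 without unablated replicate 1 and 0.24 without ablated replicate 2. hspa5, the main chaperone of the endoplasmic reticulum, stood at 320 ± 143 against 47.4 ± 42.2 CPM (adjusted p = 0.13, blocked adjusted p = 0.0012).

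Oxidative phosphorylation genes were higher in 37 of 40 cases at 4 dpi, with a median of 0.58, no call over all genes and 12 higher with the block (adjusted p = 5e-05, adjusted p = 0.57 with an estimated correlation). Eye field genes had a median of -1.02 over 28 genes, with no call over all genes and 1 lower with the block (adjusted p = 0.01, adjusted p = 0.65 with an estimated correlation). Without unablated replicate 2 or ablated replicate 3 that list gave adjusted p = 0.4 and 0.14. Lens markers were lower in 17 of 18 cases, with a median of -5.33 (adjusted p = 5e-05, adjusted p = 0.57 with an estimated correlation). None was called over all genes or with the block, 13 were lower adjusted over the list alone, and without unablated replicate 3 the list gave adjusted p = 0.38. That library held 399 CPM of lens markers in sum, against 11.4 and 14.5 CPM in the other unablated libraries. The injury response list did not pass (adjusted p = 0.051), although hbegfa rose. It passed without ablated replicate 1 or unablated replicate 3 (adjusted p = 0.011 and 0.0028). rpe65a stood at 8630 ± 3290 against 13800 ± 1840 CPM (adjusted p = 0.7, blocked adjusted p = 0.13). RPE and melanin genes did not pass as lists (adjusted p = 0.3 and 0.81). Median and test differed in sign for cell cycle, complement, Mueller glia and Wnt genes, none of which passed (adjusted p = 0.48, 0.58, 0.94 and 0.52).

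In the edgeR test 19 genes passed at 4 dpi, 13 higher and 6 lower, and 2354 had an unadjusted p under 0.05. The block called 1732 genes, 942 higher and 790 lower, and kept all 19. The count was 0 without unablated replicate 1, ablated replicate 1, ablated replicate 2, unablated replicate 3 or ablated replicate 3, where from 1725 to 2035 genes had an unadjusted p under 0.05, and 27 without unablated replicate 2. DESeq2 called 717 genes and voom 1062 with all libraries. The share of higher genes was 68.4% and 79.4% when tested on TPM. With voom, run without TMM factors, the median of all genes moved from -0.07 to 0.20.

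At 7 dpi, in the last comparison of ablated with unablated larvae, no single gene passed in edgeR. rpe65a stood at 16600 ± 5200 CPM in ablated and 19700 ± 7380 CPM in unablated libraries (adjusted p = 0.97), and cxcl18b at 214 ± 163 against 120 ± 130 CPM (adjusted p = 0.91). btg2 stood at 177 ± 73.7 against 618 ± 201 CPM (log2 fold change -1.80, SE 0.48, adjusted p = 0.71, blocked adjusted p = 0.13). Macrophage and microglia markers were higher in 31 of 32 cases, with a median of 2.41 (adjusted p = 2.4e-05, adjusted p = 0.57 with an estimated correlation). Ablated replicate 3 alone held 2210 CPM of macrophage markers other than apoeb in sum, against 349 and 93.8 CPM in the other ablated libraries, and without it the list gave adjusted p = 0.32.

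Lists with an upward call at 7 dpi were also interferon response, with a median of 0.53 and 2 of 24 genes higher adjusted over the list alone (adjusted p = 0.0023, adjusted p = 0.38 with an estimated correlation), and oxidative phosphorylation, higher in 36 of 40 cases with a median of 0.39 (adjusted p = 0.0023, adjusted p = 0.58 with an estimated correlation). The latter gave 0.091 without ablated replicate 2. Cytokines and chemokines had a median of 0.59 and 1 gene higher adjusted over the list alone (adjusted p = 0.024, adjusted p = 0.56 with an estimated correlation). They gave 0.33, 0.09 and 0.21 without unablated replicate 1, ablated replicate 2 or ablated replicate 3. Cell cycle genes were higher in 33 of 34 cases, with a median of 2.13 (adjusted p = 0.047, adjusted p = 0.76 with an estimated correlation). They gave 0.46 and 0.19 without unablated replicate 2 or 3, and the direction turned without ablated replicate 1 (adjusted p = 0.05), which held 2570 CPM of these genes against 980 and 766 CPM in the other ablated libraries.

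Photoreceptor markers were lower in 31 of 36 cases at 7 dpi, with a median of -0.92 (adjusted p = 0.0037, adjusted p = 0.65 with an estimated correlation), and rod opsin rho stood at 126 ± 105 against 693 ± 693 CPM (adjusted p = 0.8). The list gave 0.33, 0.31, 0.055 and 0.17 without unablated replicate 1, unablated replicate 2, ablated replicate 2 or ablated replicate 3. Retinal neuron markers had a median of -1.29 (adjusted p = 0.031, adjusted p = 0.58 with an estimated correlation), and gave 0.28 and 0.52 without ablated replicate 1 or unablated replicate 2. Ribosomal proteins were higher in 51 of 51 cases, with a median of 0.43, and passed with the block alone (adjusted p = 0.08, blocked adjusted p = 0.00017), but not with the block and an estimated correlation (blocked adjusted p = 0.74). RPE and melanin genes did not pass (adjusted p = 0.4 and 0.86). Median and test differed in sign for lymphocyte, lens, matrix and cholesterol genes, none of which passed (adjusted p = 0.54, 0.67, 0.86 and 0.58). None of these list members was called over all genes with or without the block.

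The edgeR count of 0 at 7 dpi stood beside 1328 genes with an unadjusted p under 0.05. DESeq2 called 133 genes, voom 0 and the test on TPM 1, and leaving out unablated replicate 1 or ablated replicate 1 gave 3 and 1. The block called 1 gene, si:dkeyp-120h9.1 (chromosome 19, 32155791 to 32178302), named here after its values were seen, at 21.9 ± 5.81 against 109 ± 22.2 CPM (blocked log2 fold change -2.33, SE 0.23, blocked adjusted p = 0.014).

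Genes called at 2 and 4 dpi overlapped. Of the 19 genes called at 4 dpi 6 were also higher at 2 dpi, hbegfa, aanat1 and vmp1 among them, where chance would give 0.181 (hypergeometric exact test, p = 1.1e-08). Another 4 were lower at both times, col9a1a, phyhipla, tnk2b and gatsl2, where chance would give 0.0514 (exact test, p = 7.7e-08), and none moved in opposite directions. This overlap was empty when unablated 4 dpi replicate 1 or 3 or any ablated 4 dpi replicate was left out, since 0 genes then passed at 4 dpi. With the block 539 genes were higher and 455 lower at both times, and 9 went in opposite directions. Of the 452 genes called at 2 dpi 441 kept their sign at 4 dpi (97.6%) and 353 at 7 dpi (78.1%), against 66.8% and 55.7% of all genes. Fold changes correlated across 20093 genes at r = 0.426 (rho = 0.454) between 2 and 4 dpi, at r = 0.1 (rho = 0.133) between 2 and 7 dpi and at r = 0.285 (rho = 0.349) between 4 and 7 dpi.

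**Figure D3:**
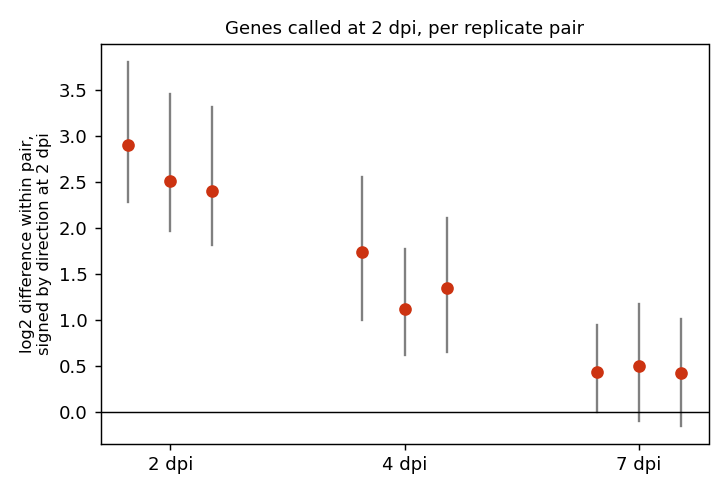
Median direction-aligned log2 difference (ablated minus unablated library of the same replicate number) over the 452 genes called at 2 dpi, for each pair at 2, 4 and 7 dpi; bars span the quartiles over genes. The highest pair median was 2.90 at 2 dpi, 1.74 at 4 dpi and 0.50 at 7 dpi, and the genes were chosen for their size at 2 dpi.

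Whether the effect of ablation differed between times was tested directly. Without the block no gene passed for 4 against 2 dpi, 7 against 2 dpi or 7 against 4 dpi in edgeR, where 919, 2060 and 697 genes had an unadjusted p under 0.05. DESeq2 called 26, 285 and 29, voom 0 each and the test on TPM 1, 1 and 0. For 7 against 2 dpi 2 genes passed without unablated 7 dpi replicate 1, and for 7 against 4 dpi 1 gene without unablated 4 dpi replicate 2. With the block 16 genes differed between 4 and 2 dpi, 862 between 7 and 2 dpi, and 0 between 7 and 4 dpi, where 1672 had an unadjusted p under 0.05. Leaving out a pair gave 1 to 12 genes for 4 against 2 dpi, 122 to 757 for 7 against 2 dpi and 0 to 23 for 7 against 4 dpi. The effect on ncl, the nucleolin gene, was lower at 4 than at 2 dpi by a blocked log2 difference of -2.60 (SE 0.35, blocked adjusted p = 0.042). That on npm1a, the nucleophosmin gene, was smaller at 7 than at 2 dpi by -3.62 (SE 0.37, blocked adjusted p = 0.0055). cbx7a, a Polycomb gene, had differences of -4.66 at 4 dpi and -5.46 at 7 dpi against 2 dpi (blocked adjusted p = 0.0026 and 0.00062). The effect on the calreticulin gene calr was larger at 4 than at 2 dpi by 2.37 (SE 0.32, blocked adjusted p = 0.042), and that on fabp7a, a glial fatty acid-binding protein gene, was higher at 7 than at 2 dpi by 5.29 (SE 0.62, blocked adjusted p = 0.0058).

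Unablated larvae at 7 and at 2 dpi were compared to describe the baseline with age. slc43a2b rose by a log2 fold change of 7.20 (adjusted p = 0.003). The proteasome genes psmd10 and psma3 fell from 161 ± 75.9 to 10.2 ± 5.1 CPM and from 1520 ± 633 to 179 ± 77.9 CPM, log2 fold changes of -3.97 (SE 0.54, adjusted p = 0.01) and -3.08 (SE 0.49, adjusted p = 0.023), and tfam, which encodes a mitochondrial transcription factor, fell from 64.2 ± 26 to 8.65 ± 3.77 CPM (adjusted p = 0.023). These genes were named after their values were seen. Of 40 oxidative phosphorylation genes 13 fell, and 30 adjusted over the list alone (adjusted p = 1.1e-11, adjusted p = 0.69 with an estimated correlation). Of 34 cell cycle genes 2 fell, and 4 adjusted over the list alone, with a median of -3.07 (adjusted p = 2.4e-09, adjusted p = 0.69 with an estimated correlation). Lens and eye field genes also stood lower as lists (adjusted p = 0.00012 and 0.01, adjusted p = 0.69 and 0.89 with an estimated correlation). Injury response and other pigment cell genes stood higher (adjusted p = 0.026 and 0.042, both adjusted p = 0.69 with an estimated correlation). Of 32 injury response genes 3 rose, and 6 adjusted over the list alone.

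In all 776 genes passed between unablated 7 and 2 dpi libraries, 232 higher and 544 lower, and 4224 had an unadjusted p under 0.05. The count was 2 without 2 dpi replicate 2, 0 without 2 dpi replicate 3, 2 without 7 dpi replicate 2, 1 without 7 dpi replicate 3 and 1369 without 2 dpi replicate 1. The direction of this comparison depended on the method, since 29.9% of called genes were higher in edgeR, 71.5% with voom and 72.8% on TPM. The median of all genes was 0.13, 0.68 and 0.33. Scaling cannot be excluded as the reason, since voom and the test on TPM were run without TMM factors, and edgeR with DESeq2 size factors gave 24.7% higher. TMM factors of the unablated libraries were 1.05, 0.761 and 0.637 at 2 dpi and 1.07, 1.05 and 1.05 at 7 dpi. Where 2 and 7 dpi libraries carry a date in their sequencing names, the dates differ, so age and preparation cannot be fully told apart.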

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

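The tests of apoeb, of eye field genes and of genes called at 4 dpi were chosen after the results were seen. The block, the estimated correlation and leaving out single libraries were applied to list differences between times after those had been called.

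With the block 16 genes had an ablation effect that differed between 4 and 2 dpi, and 862 between 7 and 2 dpi, where the fit without it gave 0 for both. For 7 against 2 dpi 4 of 32 exchanges of pair labels, the real one included, gave as many genes, and the highest other count was 2402. Exchanges of 7 dpi pairs alone leave the 2 dpi effect in place and gave 476 to 2402 genes, and all exchanges that touched a 2 dpi pair gave 0. They are therefore no test of whether the effects differ, and chance was not judged for the count of 862.

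Several lists differed in their ablation effect between 4 and 2 dpi. Effects were higher at 4 dpi for cell cycle genes by a median of 0.94 (adjusted p = 1.6e-05), for macrophage markers by 3.87 (4.4e-06), for photoreceptor markers by 2.64 (9.9e-07) and for eye field genes by 1.44 (8.3e-05), and these calls held without any single library. With an estimated correlation each of these 4 lists gave adjusted p = 0.66. Lysosome genes were higher by 0.59 (0.0065, 0.66 with an estimated correlation), but gave 0.2 without unablated 2 dpi replicate 1. Mueller glia markers were higher by 1.66 (0.015, 0.42 with an estimated correlation), and gave 0.054 without unablated 4 dpi replicate 1 and 0.062 without ablated 4 dpi replicate 2. Fibroblast markers were higher by 1.62 (0.014, 0.5 with an estimated correlation), and gave 0.062 without unablated 2 dpi replicate 1, 0.062 without unablated 4 dpi replicate 2 and 0.091 without ablated 4 dpi replicate 2.

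Complement (0.74, adjusted p = 0.049) and keratinocyte markers (2.53, adjusted p = 0.028) lost the call between 4 and 2 dpi with the block (0.16 and 0.14) and with an estimated correlation (0.5 and 0.66). Complement also lost it without unablated replicate 1 (0.2), ablated replicate 1 (0.11) or ablated replicate 2 (0.051) of 2 dpi. The same held at 4 dpi without ablated replicate 1 (0.12), unablated replicate 2 (0.067), ablated replicate 2 (0.08) or unablated replicate 3 (0.16). Keratinocyte markers lost it without unablated replicate 1 (0.62), ablated replicate 1 (0.17) or ablated replicate 3 (0.1) of 2 dpi. At 4 dpi they lost it without unablated replicate 1 (0.077), ablated replicate 1 (0.074), unablated replicate 2 (0.25) or ablated replicate 3 (0.079). The block added ribosomal proteins, with a median of -0.41 (0.0089, 0.81 with an estimated correlation).

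Between 7 and 2 dpi effects were higher at 7 dpi for eye field genes by a median of 3.74 (adjusted p = 8.1e-09, and 0.5 with an estimated correlation), a call that held without any single library. Cell cycle genes were higher by 4.37 (1.6e-05), but gave 0.14 without ablated 7 dpi replicate 1, and macrophage markers by 4.02 (0.00037), but gave 0.2 without ablated 7 dpi replicate 3. Both gave 0.66 with an estimated correlation. Lens markers were higher by 3.34 (0.004, 0.66 with an estimated correlation), and gave 0.093 without ablated 7 dpi replicate 2. Mueller glia markers were higher by 1.38 (0.018, 0.42 with an estimated correlation), and gave 0.19 without unablated 7 dpi replicate 1 and 0.12 without ablated 7 dpi replicate 3. Effects were lower for injury response genes, by a median of -1.16 (0.00082, and 0.051 without ablated 7 dpi replicate 1), and for heat shock genes, by -1.41 (0.0038, and 0.052 without unablated 2 dpi replicate 1), and both gave 0.5 with an estimated correlation.

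Between 7 and 4 dpi effects were lower at 7 dpi for heat shock genes, by a median of -1.74 (adjusted p = 8.3e-05, and 0.42 with an estimated correlation), a call that held without any single library. Lens markers were higher by 4.91 (2e-04, 0.66 with an estimated correlation), but gave 0.77 without unablated 4 dpi replicate 3, the library with 399 CPM of lens markers. Eye field genes were higher by 1.76 (0.00041, 0.66 with an estimated correlation), and gave 0.11 without unablated 4 dpi replicate 2, 0.083 without ablated 7 dpi replicate 1 and 0.11 without unablated 7 dpi replicate 3. Injury response genes were lower, by -0.66 (0.0029, 0.5 with an estimated correlation), and gave 0.058 without unablated 4 dpi replicate 2 and 0.24 without ablated 7 dpi replicate 1. Photoreceptor markers were lower, by -1.77 (0.0041, 0.77 with an estimated correlation). They gave 0.52 without ablated 4 dpi replicate 2, 0.16 without unablated 4 dpi replicate 3, 0.3 without unablated 7 dpi replicate 1, 0.3 without unablated 7 dpi replicate 2 and 0.18 without ablated 7 dpi replicate 3. Wnt genes were lower, by -0.46 (0.0072, 0.66 with an estimated correlation). They gave 0.054, 0.09, 0.15 and 0.14 at 4 dpi without unablated replicate 1, ablated replicate 1, ablated replicate 2 and unablated replicate 3, and 0.25, 0.11 and 0.3 at 7 dpi without unablated replicate 1, ablated replicate 2 and ablated replicate 3.

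With an estimated correlation none of these list differences passed, and adjusted p ran from 0.42 to 0.77.

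Fewer genes passed at 7 than at 2 dpi. Larger spread between 7 dpi libraries was weighed by the ratio of the 7 dpi to the 2 dpi direction-aligned difference. Over the genes called at 2 dpi the ratio was 0.175, but these were chosen for their size at 2 dpi. Over 1732 genes called with the block at 4 dpi, a set chosen after the first ratio was seen, it was 0.53, which lies between the bounds set for either answer. A lower depth is not the reason, since thinning every library to 21.9 M counts gave 519 genes at 2 dpi and 0 at 7 dpi.

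Eye field genes were lower in ablated libraries at 2 dpi, and a smaller share of neural retina cells among eGFP-positive cells could account for it. If so, markers of mature retina that share no member with that list should also be lower, and the highest of their 3 medians was -1.331, for Mueller glia, with -2.52 for photoreceptors and -2.08 for retinal neurons. Of the mature markers 27 of 36, 13 of 23 and 8 of 14 reached 5 CPM in unablated libraries. Of the 3 most abundant in each list, gnb1a stood at 149 ± 24.1 against 147 ± 5.71 CPM and slc6a9 at 144 ± 59.9 against 167 ± 27.7 CPM. By mean grm6b (41.4 ± 12.3 against 29.5 ± 17.7 CPM) and glulb (693 ± 494 against 553 ± 279 CPM) stood higher. Lower were glula and fabp7a, at 489 ± 384 against 2770 ± 2310 and 96.8 ± 57.5 against 2100 ± 1960 CPM. So were gngt2b (62 ± 58.7 against 414 ± 564 CPM), opn1sw1 (5.07 ± 2.79 against 206 ± 335 CPM) and snap25b (3.13 ± 1.36 against 27.3 ± 16.4 CPM). The prediction was written after the medians were known, so carry-over may explain the fall and a change in RPE cells is not excluded.

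apoeb stood at 2590 ± 603 against 175 ± 237 CPM at 4 dpi, and macrophage RNA in the eGFP-positive sort might be its source. Relative to the library richest in macrophage markers, ablated 7 dpi replicate 3, the ratio of apoeb to the other 31 markers in ablated 4 dpi libraries was 3.62, 1.7 and 2.18, around the 3-fold bound written after the values were known. In unablated 4 dpi libraries it was 0.123, 0.522 and 0.125, so apoeb did not keep 1 proportion to the other markers across groups. Abundant markers were higher by mean as well, hexb at 84.7 ± 4.22 against 45.8 ± 11.8 CPM and apoc1 at 36.2 ± 31.9 against 4.66 ± 7.61 CPM. Of the 31 markers 9 reached 5 CPM in unablated libraries and 4 stand in another list. Macrophages and RPE cells could both be the source.

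Splits of libraries were too few to judge chance for ablation at 2 dpi, at 4 dpi and for unablated time, where 1 of 10 splits reached the real counts of 452, 19 and 776 and the highest other count was 0. At 7 dpi all 10 of 10 reached the real count of 0 and the highest other was 1. With the block splits were too few at each time, where 1 of 4 reached the real counts of 2901, 1732 and 1 and the highest other was 0. For differences between times without the block 60 of 60 splits reached the real count of 0, with a highest other of 2, 2 and 5. Every split reaches a count of 0, so where the real count was 0 the splits could not judge chance.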

How the results depend on the processing

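The alternatives were fixed before the data were seen, apart from those applied to the block and to differences between times, which were added later.

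At 2 dpi 452 genes became 1759 with DESeq2, 2537 with voom, 78 with only the times compared and 2901 with the block, and 19 to 252 when 1 library was left out. At 4 dpi 19 genes became 35 with no filter, 717 with DESeq2, 1062 with voom, 220 with only the times compared, 1732 with the block, 10 lacking first replicates (2 of them shared) and 228 on TPM, and 0 to 27 when 1 library was left out. At 7 dpi 0 genes became 133 with DESeq2, 1 with the block and 1 on TPM, and 0 to 3 when 1 library was left out. The cause was not tested for any of these, though DESeq2 made 80 to 89 false calls in simulated data and voom was run without TMM factors.

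For effects that differ between 4 and 2 dpi the count of 0 became 26 with DESeq2, 16 with the block and 1 on TPM. Between 7 and 2 dpi it became 285 with DESeq2, 862 with the block and 1 on TPM, and 0 to 2 when 1 library was left out. Between 7 and 4 dpi it became 29 with DESeq2, and 0 to 1 when 1 library was left out. For unablated time 776 became 2569 with DESeq2, 4064 with voom, 0 with only the times compared and 2668 lacking first replicates, and 0 to 1369 when 1 library was left out. The overlap of 10 genes became 342 with DESeq2, 994 with the block and 18 with no filter.

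The 25 list calls became 0 with an estimated correlation and 0 with fry. With the block fry called 4 lists at 2 dpi, cytokines, Mueller glia and eye field (each adjusted p = 0.023) and retinal neurons (0.026). It called 2 at 4 dpi, cytokines and oxidative phosphorylation (both 0.023), and 0 at 7 dpi. Taken without regard to direction, fry without the block called 10, 11 and 2 lists at 2, 4 and 7 dpi. The 49 calls of named genes became 28 with only the times compared, 18 lacking first replicates and 30 on TPM, and 17 to 49 when 1 library was left out. The direction of the list cell cycle at 7 dpi turned lacking first replicates (adjusted p = 0.71) and without ablated replicate 1 (0.05), and adjusted p ran from 9.8e-06 to 0.46 when 1 library was left out. Among ablation effects of named genes and lists the block ended the calls of vsx1 at 2 dpi and interferon genes at 4 dpi. It brought 159 tests of named genes and 3 of lists under the threshold, and changed no other call. Genes were also named from calls of the block, so part of the gain in named genes was set in advance.

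For genes changed by ablation at 2 dpi, replicate block included, leaving out a pair gave 1191 to 1465. It gave 339 to 925 at 4 dpi and 0 to 4 at 7 dpi. For differences it gave 1 to 12 between 4 and 2 dpi and 122 to 757 between 7 and 2 dpi, and 0 to 23 between 7 and 4 dpi.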

Other observations

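The gene groups in this part were chosen after the genes that passed had been read, and the predictions for them were written before the tested values were seen. npm1a, the nucleophosmin gene, rose from 112 ± 29.5 to 1800 ± 462 CPM (log2 fold change 4.00, SE 0.65, adjusted p = 0.015), and mrto4, a ribosome assembly gene, from 33.7 ± 17.4 to 429 ± 81.5 CPM (log2 fold change 3.67, SE 0.57, adjusted p = 0.015). fbl, the fibrillarin gene, rose from 94 ± 25 to 546 ± 76.7 CPM (log2 fold change 2.54, SE 0.47, adjusted p = 0.016).

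Of 79 ribosome biogenesis factors 46 rose at 2 dpi and none fell, with a median of 2.36. The count was 17 without unablated replicate 1, 0 without unablated replicate 2, 23 without ablated replicate 2 and 10 without unablated replicate 3, while the median stayed between 2.22 and 2.48. The group was drawn from this same time, so its p there is not a test, and the separate 4 dpi libraries were used. There the median was 0.73, no member passed, and unadjusted tests gave p = 1.2e-09 for camera at the preset, 0.15 with an estimated correlation and 0.04 for the rotation test fry. With the block 25 members were higher and 3 lower at 4 dpi. The value for fry rose to 0.1, 0.067, 0.072 and 0.069 without unablated replicate 1, ablated replicate 1, ablated replicate 2 and ablated replicate 3. The tests thus differ, and whether the group as a whole stayed higher at 4 dpi is left open.

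Chaperones of the endoplasmic reticulum were among the genes that rose at 4 dpi, 3 of 32, or 14 with the block, with manf and calr3b passing and a median of 0.72. Without the block the count was 0 when unablated replicate 1 or 3 or any ablated replicate was left out. In the separate 2 dpi libraries the median was 0.52 and unadjusted tests gave p = 0.0041 for camera at the preset, 0.23 with an estimated correlation and 0.08 for fry. With the block 7 members were higher and none lower at 2 dpi. Without ablated replicate 1 camera at the preset gave 0.06, and whether the group was already higher at 2 dpi is left open.

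Proteasome subunits were lower at 7 than at 2 dpi in unablated libraries, 29 of 34, with a median of -2.16. That count was 1 without 2 dpi replicate 2 and 0 without 2 dpi replicate 3, 7 dpi replicate 2 or 7 dpi replicate 3, while the median ran from -2.02 to -2.54. The separate ablated libraries had 29 of 34 lower as well, with a median of -2.09 (p = 0.01 with an estimated correlation, and 0.014 to 0.023 when 1 library was left out). Their count was 15 without 2 dpi replicate 2 and 18, 19 and 13 without 7 dpi replicates 1, 2 and 3. A fall between unablated groups cannot come from ablation, and ablated libraries share ages and dates with their pairs. Age and preparation date therefore cannot be fully told apart. Against unablated libraries of the same time, subunits had a median of 0.84 at 4 dpi, with 16 higher and none lower with the block. Unadjusted tests there gave p = 4.6e-08 for camera at the preset, 0.13 with an estimated correlation and 0.025 for fry. At 2 and 7 dpi medians were 0.33 and 0.47, with none called with the block (p = 0.54 and 0.17 for camera with an estimated correlation).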
